A study of Dinoroseobacter shibae DFL 12 = DSM 16493 with 12 samples.

How the data were processed

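Total RNA of Dinoroseobacter shibae DFL 12 was measured on 2-colour Agilent arrays. On each of the 12 arrays a wild-type sample was labelled with Cy3 and a sample of the delta-luxI1 mutant carrying plasmid pDP1, which overexpresses luxI1 in trans, was labelled with Cy5, per the labels. The plasmid-bearing mutant is called the complemented strain. Samples were grouped as the labels give them, into 5 exponential densities (an OD600 of 0.1 or 0.2 on slide 1, and of 0.4, 0.6 or 0.8 on slide 2) and stationary phase (6 h after the maximum OD600), with 2 biological replicates per group. The same dye went to the same strain on all arrays, so a dye effect that is constant for an ID cannot be separated from a strain difference that is constant over densities. Such an effect cancels in differences between densities and within a strain. The arrays came from 2 slides, which were also the 2 scans: slide 1 held the 4 arrays of OD600 0.1 and 0.2, and slide 2 held the other 8.

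The deposited scanner files give each spot's median brightness in each colour and that of its local background, in intensity units. Agilent Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09 made them, per the file headers. They also hold the scanner software's background-subtracted, dye-normalized signals (intensity) and log10 ratios of Cy5 over Cy3, per the file headers. The authors' series matrix holds log2 ratios after normalization with limma, whose version is not stated. Its ratios are wild-type over complemented strain, with the mean of each array at 0: across spots they correlated with the scanner's Cy5 over Cy3 ratios at r from -0.945 to -0.768, and with the ratios computed here at r from -0.997 to -0.976. The column medians of the matrix lay between -0.0280 and 0.0361. Its values entered as an alternative, with the sign turned.

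Each array held 14999 spots, of which 687 were controls. The other 14312 spots carried 12476 probes for 4102 IDs. Of the probes, 12272 had 1 spot and 204 had 10 spots, and 4007 IDs had 3 probes. The array IDs have the form RDRS followed by a number. They matched 0 entries of the reference gene table, so the files do not pair them with gene names, and which ID is luxI1 is not given. For this reason at most 2 IDs higher and 2 lower are named per comparison, in place of the longer lists planned before the data were examined. Among IDs with an adjusted p under 0.05, those with the highest and the lowest log2 value were taken. In the mean strain ratio and at single densities they also had to have the same sign on every array concerned. For the stationary minus exponential difference, both stationary arrays had to lie beyond the exponential mean in the same direction. For the F test the 2 IDs with the highest F were taken. The planned gene lists by function, the lists by replicon and the check on luxI1 could not be run without names. Instead, 2 groups of IDs were taken from the names of their probes, after the files were seen: PhotoGC (168 probes, 57 IDs) and QSense (36 probes, 12 IDs), names that the files do not spell out. From these groups a few IDs are named as examples, chosen after their values were seen.

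Analysis used R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8). Median signals were background-corrected by normexp with an offset of 50. Mean signals had been planned, but the files hold no mean signal. Loess normalization within arrays gave control spots and spots marked as outliers by the scanner software a weight of 0, and those outlier spots were then left out. No scaling between arrays was applied. Spots were averaged to probes and probes to IDs. The ratio is log2 of Cy5 over Cy3, complemented strain over wild-type, so positive values mean more signal in the complemented strain. This sign is opposite to that of the deposited matrix. An ID was tested when it was well above background by the scanner software's criterion in at least 1 channel on both arrays of at least 1 group. This kept 3589 IDs and left out 513. On an array an ID counted as well above background when at least 0.5 of the spots of at least 1 of its probes passed.

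Group means were fitted with lmFit and eBayes over all 12 arrays, which share 1 estimate of the spread per ID (6 residual degrees of freedom). Contrasts were the mean of the 6 groups, each group, stationary minus the mean of the 5 exponential densities, the slope on log2 OD600 over those 5, and a moderated F test of the differences between groups. For the course of growth within each strain, the 24 channels were normalized with Aquantile and fitted with lmscFit, with an intra-spot correlation of 0.217. An estimate failed for 12 IDs, which were left out of that average. The p-values were adjusted by Benjamini-Hochberg over the 3589 IDs and called under 0.05, and all tests are two-sided. The 2 probe-name groups were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the 2 groups. Where all arrays of a strain in a group fell short of well above background, folds are given as lower limits from the background level, or not at all. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

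The IDs well above background numbered 72.2% to 77.5% per array for wild-type in exponential phase and 38.9% to 47.5% in stationary phase. In the complemented strain they numbered 76.4% to 85.6% and 52.3% to 55.4%. No spot was saturated. For arrays the precision rests on their number, which is 2 per group. On simulated data of the same design, the test of the mean ratio recovered 98.4% of IDs changed 1.5-fold and 100% of those changed 2-fold, with 11 false calls among 3389 unchanged IDs. For the stationary minus exponential difference it recovered 65.3% at 1.5-fold and 92.1% at 2-fold, with 3 false calls. The simulation gave an ID the same spread on all arrays. In the real data the ratios of replicates differed by 0.780 at OD600 0.8 and by 0.114 to 0.171 elsewhere (root mean square over IDs). These rates may therefore not hold for the real arrays.

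Alternatives fixed before the data were examined were no background correction, the scanner software's processed signals, median centring, scaling between arrays, no filter, a stricter filter (both channels on all arrays, 1455 IDs), the median of the probes, the matrix values, array weights, the replicate number as a block, the slide as a block, values within slides, only the arrays of a density, stricter thresholds, quantile normalization, and leaving out each array in turn. Leaving out both OD600 0.8 arrays, and the growth courses within slide 2, were added after seeing the data.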

Results

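The transcriptomes of wild-type D. shibae DFL 12 and of the delta-luxI1 mutant that overexpresses luxI1 from plasmid pDP1 were compared through growth. LuxI-type enzymes make acyl-homoserine lactones, the signals of quorum sensing in many Gram-negative bacteria. The design asks how the complemented strain differs from wild-type, and how that difference depends on cell density. Cultures were sampled in exponential phase, at OD600 0.1 to 0.8, and 6 h after the maximum OD600, with 2 arrays per group and 12 in all, each carrying both strains. Median spot brightness per array was 1826.75 to 4911.5 in Cy3 (wild-type) and 3724 to 6955 in Cy5 (complemented strain), lowest in stationary phase for both strains. Values are log2 ratios of complemented strain over wild-type, so a positive value means more transcript signal in the complemented strain. The deposited matrix has the opposite sign. Because wild-type was always in Cy3, a constant dye effect is part of every ratio within a group and drops out of differences between groups.

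The files do not say which array ID is luxI1, so the gene that differs between the strains by construction could not be looked up. Probes named QSense identify 12 IDs, and in the mean over the 6 groups 8 of these were higher in the complemented strain, 2 were lower and 2 did not pass the test. RDRS00311, one of the QSense IDs, had a mean ratio of 5.02 ± 0.07 on the log2 scale (SE, n = 12 arrays), with an adjusted p of 9.36e-10. It was higher on 12 of 12 arrays, at 4.30 to 7.61, the stationary values being taken over a wild-type signal not well above background. RDRS02845 was 1.93-fold higher (log2 0.95 ± 0.03, SE), RDRS02846 1.81-fold (0.86 ± 0.05) and RDRS00310 1.80-fold (0.85 ± 0.02), each on 12 of 12 arrays. For RDRS02845 the wild-type signal was not well above background in stationary phase, where the ratio is at least 1.63-fold. Of the 2 lower members, RDRS01811 stood at -0.22 and was higher on 0 of 12 arrays. RDRS01815 stood at -0.10 but was higher on 6 of 12 arrays, with values of -0.02 to 0.15 at OD600 0.1 to 0.6 and -0.64 at OD600 0.8. For both of these IDs neither strain was well above background in stationary phase. As a group the QSense IDs had a median of 0.25 against -0.04 for all IDs, and camera gave an adjusted p of 0.000736. The group includes RDRS00311 at 5.02, and its mean was 0.69. No test without that ID is given, and whether it is luxI1 is not known. With an estimated correlation the adjusted p was 0.0421. Adjusted over the list alone, the same numbers of IDs, 8 and 2, passed.

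Over all densities, 2 IDs stood far above the rest. RDRS03868 was higher in the complemented strain in the mean of the groups (adjusted p = 8.81e-10) and on 12 of 12 arrays. Its fitted mean of 4.96 ± 0.06 (SE, n = 12 arrays) averages unlike groups, near 6.6 up to OD600 0.6, 1.99 at OD600 0.8 and a fitted 1.52 in stationary phase over a wild-type signal not well above background, so no fold is given for it. RDRS00311 was described above. Among the lower IDs, RDRS00022 stood at -1.48 ± 0.04 and RDRS00772 at -1.10 ± 0.06, both below 0 on every array. In all, 1974 of 3589 IDs differed between the strains, 855 higher and 1119 lower. Most of these differences were small: 36 of the higher and 4 of the lower IDs exceeded 2-fold. Within slide 1 the count was 2459 (1288 higher, 1171 lower) and within slide 2 it was 1500 (622 and 878), so the majority lay the other way within slide 1. A constant dye effect in any of these IDs cannot be told apart from a constant strain difference, since no array had the dyes exchanged.

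**Figure D1:**
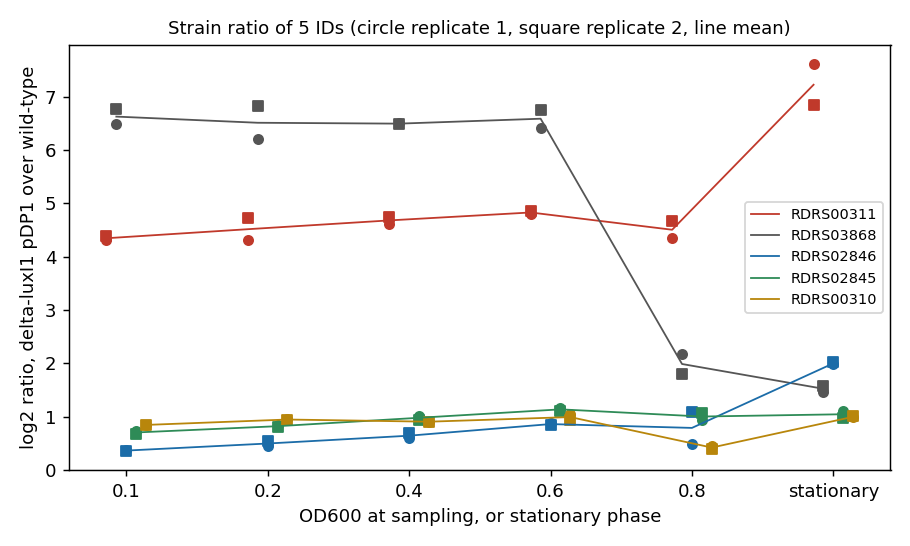
Log2 ratio of complemented strain over wild-type (y axis) by OD600 at sampling or stationary phase (x axis) for RDRS00311, RDRS03868, RDRS02846, RDRS02845 and RDRS00310, with circles for replicate 1, squares for replicate 2 and lines through the means. RDRS03868 stands near 6.6 up to OD600 0.6 and at 1.99 at OD600 0.8, while RDRS00311 stands highest in stationary phase, at 7.23, where its wild-type signal is not well above background and scaling between arrays takes the difference from exponential phase to -0.02.

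At OD600 0.1 to 0.6 the same IDs led at each density. RDRS03868 was 98.9-fold higher in the complemented strain at OD600 0.1, 91.3-fold at 0.2, 90.2-fold at 0.4 and 96.2-fold at 0.6, with log2 values of 6.63, 6.51, 6.50 and 6.59 and an SE of 0.16 for each (n = 2). RDRS00311 was 20.3-fold, 22.9-fold, 25.6-fold and 28.4-fold higher at these densities. RDRS00022 stood at -1.73, -1.69, -1.61 and -1.52 (SE 0.11). RDRS00772 stood at -1.44, -1.42 and -1.34 at OD600 0.1 to 0.4, and at OD600 0.6 RDRS03275 was the other ID named as lower, at -1.32 ± 0.13. All these values passed the test and had the same sign on both arrays of the density. For RDRS03275 the signal of the complemented strain was well above background on 1 of the 2 arrays. The numbers of IDs that differed were 569 at OD600 0.1 (340 higher, 229 lower), 639 at 0.2 (380 and 259), 602 at 0.4 (331 and 271) and 583 at 0.6 (296 and 287). With the scanner software's processed signals the majority turned to lower at 0.2, 0.4 and 0.6. Between 44 and 53 IDs exceeded 2-fold at each density from OD600 0.1 to 0.6. These counts rest on a spread shared with the OD600 0.8 arrays: without both of those arrays, a comparison added after seeing the data, they were 1950, 2008, 1954 and 1945. Leaving out 1 array of the density itself lowered each to between 116 and 148 at the lowest.

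At OD600 0.8 the ratios of many IDs were wider. RDRS00311 remained 22.7-fold higher (log2 4.51 ± 0.17, SE, n = 2, adjusted p = 2.91e-06), and RDRS03868 3.96-fold higher (1.99 ± 0.16). RDRS00837 was higher in the complemented strain, at a fitted 3.20 and 1.39 on the 2 arrays. Over both arrays this is at least 2.41-fold, a lower limit because its wild-type signal was not well above background. RDRS00265 was lower, at -3.57 and -2.12 on the 2 arrays, and RDRS00266 stood at -3.15 and -1.43. RDRS00837 and RDRS00266 lost their calls with array weights, and these 2 and RDRS00265 with only the arrays of this density in the fit, while their fitted values stayed at 2.29, -2.29 and -2.84. In all, 2027 IDs passed the test (871 higher, 1156 lower), and 1996 of these had the same sign on both arrays. In the mean of the 2 arrays, 168 of the called IDs were higher and 130 lower by over 2-fold. The replicates differed far more here than at other densities. The SD of the log2 ratios over IDs was 0.900 on the replicate 1 array and 0.411 on the replicate 2 array. It was 0.326 to 0.344 at OD600 0.1 to 0.6. Of all tested IDs, 917 and 102 exceeded 2-fold on the respective arrays, and 75 did so on both in the same direction. With only these 2 arrays in the fit, 1 ID passed, and with array weights, 12.

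In stationary phase RDRS00311 was at least 41.6-fold higher in the complemented strain (fitted log2 7.23 ± 0.17, SE, n = 2), since its wild-type signal was not well above background. RDRS00272 was also higher, at 2.09 ± 0.52 (adjusted p = 0.0140), but here the wild-type background level allows no fold to be stated, and the call ended without background correction, where the value was 0.75. It also ended without either stationary array, where the value stayed at 1.99 and 2.20. Of the lower IDs, RDRS02558 was 4.46-fold lower (log2 -2.16 ± 0.08, adjusted p = 1.60e-06) and RDRS02557 was 4.32-fold lower (-2.11 ± 0.07). RDRS02557 and RDRS02558 were well above background in both strains only in this phase. The test passed 1382 IDs, 435 higher and 947 lower, of which 72 and 77 exceeded 2-fold. Without both OD600 0.8 arrays 2628 IDs passed, 1061 higher and 1567 lower, and without stationary replicate 2 the count was 610.

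The strain ratio depended on density for many IDs. RDRS03868 gave the highest F (255, adjusted p = 2.21e-05): stationary minus exponential, its log2 ratio differed by -4.12 ± 0.17 (SE). Its signal in the complemented strain fell by 3.44 from OD600 0.1 (slide 1) to 0.8 (slide 2). In stationary phase, with wild-type not well above background, RDRS03868 was at least 2.67-fold higher. RDRS02558 followed in F (140) and had a difference of -2.28 ± 0.09, although in exponential phase both strains were at background for it. The ratio of RDRS00311 was 2.65 ± 0.19 higher in stationary than in exponential phase (adjusted p = 4.53e-05), and that of RDRS00294 by a fitted 2.32 ± 0.61 (adjusted p = 0.0204). For both IDs the wild-type signal in stationary phase was not well above background, and for RDRS00294 its level allows no fold to be stated there. Scaling between arrays turned the difference of RDRS00311 to -0.02 and the lack of background correction lowered it to 1.04, and RDRS00294 lost its call without background correction, at 1.26. It also lost its call within slide 2, at 2.38, and without either stationary array, at 2.30 and 2.35. The F test passed 1018 IDs, 383 within slide 2 alone, 1990 without both OD600 0.8 arrays and 344 without stationary replicate 2. Stationary minus exponential passed 1161 (350 higher, 811 lower), 678 within slide 2 (205 and 473), 2377 without both OD600 0.8 arrays and 474 without stationary replicate 2.

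Within exponential phase the slope of the ratio on log2 OD600 passed for 317 IDs, 167 rising and 150 falling. RDRS03868 had a slope of -1.0 ± 0.06 per doubling of OD600 and RDRS00265 one of -0.56 ± 0.11, while RDRS01400 stood at 0.62 ± 0.13 and RDRS00474 at 0.46 ± 0.07 (SE). These 4 slopes rested on OD600 0.8. Without both of its arrays they were -0.02, 0.01, 0.23 and 0.07 and none passed, with adjusted p from 0.107 to 0.929. The slopes of RDRS00265, RDRS01400 and RDRS00474 also lost their calls within slide 2, where the values were -2.34, 1.94 and 1.80 on fewer arrays, and without either OD600 0.1 array, where they were between -0.56 and -0.55, 0.57 and 0.66, and 0.46 and 0.47. The call of RDRS00265 was also lost without any OD600 0.2 or 0.6 array, and that of RDRS01400 with array weights (0.62) and without any array of OD600 0.2 to 0.6 or stationary phase, with slopes of -0.57 to -0.55 and 0.58 to 0.66. Over all IDs 236 slopes passed without both OD600 0.8 arrays (102 rising, 134 falling), 2599 without OD600 0.8 replicate 2 (1073 and 1526), and 27 without OD600 0.1 replicate 2. Within slide 2 (OD600 0.4 to 0.8) 31 passed, and with the slide as a block 44. RDRS01400 was not well above background in either strain at OD600 0.2 to 0.6.

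Most IDs changed from exponential to stationary phase in each strain. In wild-type, RDRS02558 rose at least 27.3-fold (fitted log2 6.82 ± 0.08, SE) and RDRS02557 at least 20.3-fold (6.31 ± 0.07), both from background. RDRS00265 fell at least 25.4-fold (-5.33 ± 0.20) and RDRS00276 at least 12.8-fold (-5.23 ± 0.22) in wild-type. In the complemented strain RDRS00244 rose at least 9.58-fold (4.78 ± 0.20) and RDRS02558 at least 8.47-fold (4.54 ± 0.08). RDRS00265 fell 18.3-fold (-4.19 ± 0.20) and RDRS00199 fell at least 1.83-fold, with a fitted value of -3.59 ± 0.38. Of 3589 IDs, 3072 changed in wild-type (1569 up, 1503 down; 697 and 740 beyond 2-fold) and 2956 in the complemented strain (1362 up, 1594 down; 498 and 642 beyond 2-fold). Within slide 2 the counts were 2902 and 2710. With no filter the complemented strain had 1724 up and 1631 down, so its majority turned. In stationary phase 38.9% to 47.5% of IDs per array were well above background in wild-type, and 52.3% to 55.4% in the complemented strain. Called changes thus include IDs with a stationary signal not well above background. Aquantile gives the arrays equal distributions of average intensity, so the balance of rises and falls depends on it.

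The courses of the strains overlapped. From exponential to stationary phase 1292 IDs rose in both strains, 1387 fell in both, and 53 went in opposite called directions. Independence would give 595 and 668, but it is no realistic reference, since both strains shared spots and arrays and went through the same phases. This also bears on the correlation given next. The counts include IDs with a stationary signal not well above background. Over IDs, which are not independent replicates, the changes correlated with r = 0.944, and their SD was 1.30 in wild-type and 1.04 in the complemented strain. Of the 1161 IDs whose ratio differed between the phases, 621 rose in wild-type and rose less or fell in the complemented strain, and 273 fell in wild-type and fell less or rose in the complemented strain. A larger rise or fall in the complemented strain was seen for 46 and 87 IDs, and 134 did not pass in wild-type. The exponential mean includes the highest density, where both complemented samples stood apart from the lower densities (root mean square 0.846 and 0.873). Wild-type replicate 1 stood near them (0.178), but replicate 2 did not (0.812). The split may partly reflect this, and it was not counted without that density. From the mean of the lower densities, stationary samples stood at 1.35 and 1.34 in wild-type and 1.17 and 1.16 in the complemented strain.

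Changes were also seen between OD600 0.1 and 0.8. The OD600 0.1 arrays were on slide 1 and the OD600 0.8 arrays on slide 2. A slide or scan effect is therefore part of this contrast, which has no value within a slide. In the complemented strain RDRS01358 rose 10.6-fold (log2 3.41 ± 0.66, SE) and RDRS02078 9.99-fold (3.32 ± 0.29), while RDRS03868 fell 10.9-fold and RDRS03365 6.88-fold. In wild-type RDRS02580 rose 7.26-fold (2.86 ± 0.43) and RDRS02579 4.31-fold (2.11 ± 0.33). RDRS01098 stood at -1.80 and RDRS03312 at -1.50 in wild-type, values that passed but were -0.83 and -0.42 without OD600 0.8 replicate 2, and that missed the threshold without either OD600 0.1 array, at -1.84 to -1.77 and -1.53 to -1.48. The test passed 2689 IDs in the complemented strain (1262 up, 1427 down) and 975 in wild-type (668 up, 307 down). The wild-type count was 2692 without OD600 0.8 replicate 1 (1394 up, 1298 down) and 165 without OD600 0.1 replicate 2.

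The distance of each sample from its strain's mean at OD600 0.1 to 0.6, as the root mean square over IDs, shows where the replicates parted. At OD600 0.4 and 0.6, on slide 2 like OD600 0.8, wild-type stood at 0.0744 to 0.153 and the complemented strain at 0.0766 to 0.132. At OD600 0.8 the complemented strain stood at 0.846 and 0.873 in the 2 replicates. The wild-type sample of replicate 1 stood at 0.178, near the values at lower densities, and that of replicate 2 at 0.812. In stationary phase wild-type stood at 1.35 and 1.34, and the complemented strain at 1.17 and 1.16. The wild-type replicates at OD600 0.8 differed by 0.814 from each other, against 0.0667 to 0.116 in the other groups, and the complemented replicates by 0.281, against 0.106 to 0.217.

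**Figure D2:**
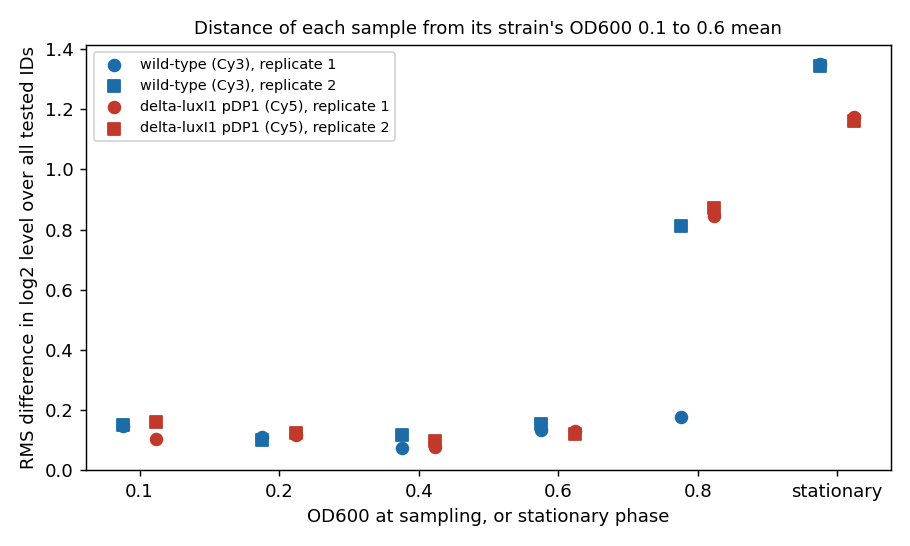
Root mean square difference in log2 level over all tested IDs (y axis) between each sample and its strain's mean at OD600 0.1 to 0.6, by OD600 or stationary phase (x axis), with wild-type in blue, the complemented strain in red, circles for replicate 1 and squares for replicate 2. At OD600 0.8 the wild-type replicates stand at 0.178 and 0.812 and the complemented ones at 0.846 and 0.873.

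Probes named PhotoGC identify 57 IDs, all of them tested. In stationary phase 35 of these were higher in the complemented strain and 4 were lower, with a median ratio of 0.52 against -0.08 for all IDs. RDRS03493 (log2 1.24 ± 0.19, SE) and RDRS03518 (1.05 ± 0.07) were higher by the most among those well above background in both strains. At OD600 0.8, where the wild-type replicates differed, 28 were higher and 4 lower, with a median of 0.35, and the medians of the single arrays were 0.60 for replicate 1 and 0.13 for replicate 2. At OD600 0.1 to 0.6 the mean of the median ratio lay between -0.06 and 0.08, and 4 to 9 members were higher and 2 to 8 lower. Stationary minus exponential, 33 members were higher and 2 lower with a median of 0.47, led by RDRS03510 (1.15 ± 0.14) and RDRS02894 (1.13 ± 0.11). Within slide 2 that median was 0.40, and without both OD600 0.8 arrays it was 0.53. In the mean over the 6 groups 30 were higher and 9 lower, with a median of 0.11, and the median was -0.02 within slide 1 and 0.20 within slide 2.

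**Figure D3:**
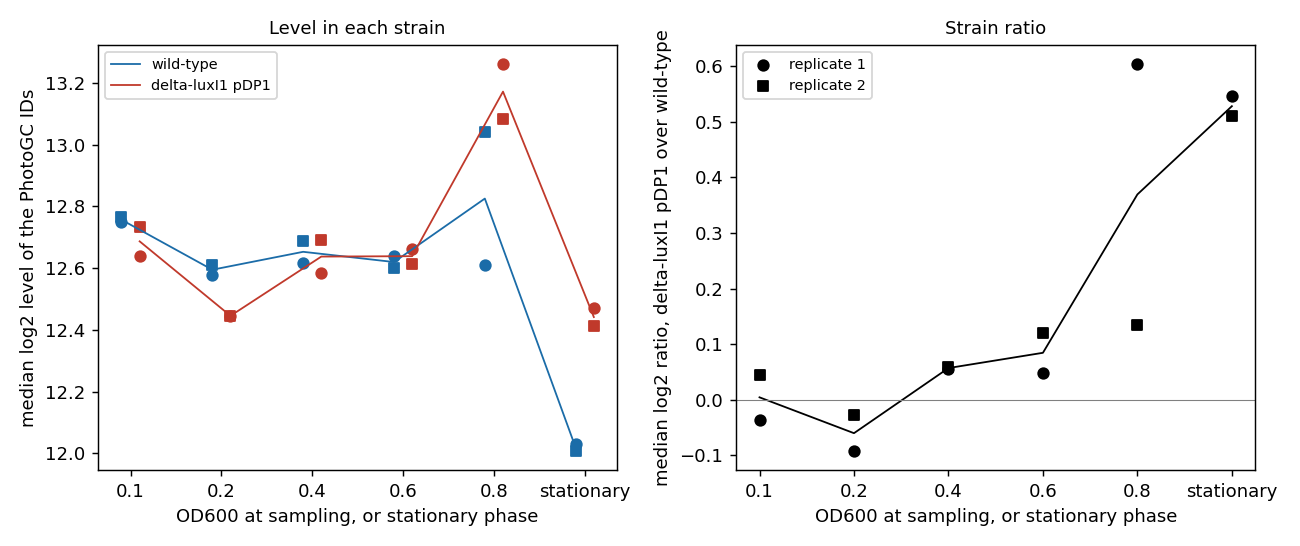
Median log2 level of the 57 PhotoGC IDs in each strain (left, y axis) and median log2 ratio of complemented strain over wild-type (right, y axis) by OD600 or stationary phase (x axes), with circles for replicate 1, squares for replicate 2 and lines through the means. The median level in stationary phase is 12.02 in wild-type and 12.44 in the complemented strain, and the mean of the ratio's median is 0.53.

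Camera gave the PhotoGC group an adjusted p of 3.30e-15 in stationary phase, 4.03e-13 for stationary minus exponential and 0.000165 for the mean ratio. With an estimated correlation these adjusted p were 0.0447, 0.0906 and 0.259, so that of the 3 the stationary call held. From exponential to stationary phase 49 of the 57 IDs fell in wild-type and 5 rose (median -0.81), among them 16 and 2 that were not well above background in stationary phase, with RDRS03510 at -1.96 ± 0.09 and RDRS03539 at -1.55 ± 0.12. In the complemented strain 38 fell, 6 of them to signals not well above background, and 2 rose (median -0.34). RDRS03493 rose by 1.36 ± 0.15 while RDRS03511 stood at -0.91 ± 0.07. Camera gave adjusted p of 5.29e-08 in wild-type and 0.00767 in the complemented strain, and with an estimated correlation 0.0998 and 0.645. By fry, which does not compare the group with other IDs, the members moved down on balance, with adjusted p of 1.40e-06 and 0.000108. From OD600 0.1 (slide 1) to 0.8 (slide 2) the complemented strain had 34 members up and 6 down (median 0.34), and wild-type 4 up and 3 down (median 0.01). Camera gave adjusted p of 0.000330 in the complemented strain and 0.590 in wild-type, and with an estimated correlation 0.419 and 0.743. The wild-type replicates stood apart here: at OD600 0.8 their median levels were 12.61 and 13.04, against 13.26 and 13.08 in the complemented strain. The slope of the strain ratio over the exponential densities, which tests the difference between the strains, was higher for 8 members and lower for 0 (median 0.11). Its adjusted p by camera was 3.23e-08, and 0.247 with an estimated correlation. The group's median ratio lay between -0.06 and 0.08 at OD600 0.1 to 0.6 and was 0.60 and 0.13 on the OD600 0.8 arrays. The group slope spans both slides, and it was not tested without the OD600 0.8 arrays or within a slide.

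For the QSense group, 3 IDs passed the test for a higher ratio in stationary than in exponential phase, none for a lower one, and 9 did not pass. RDRS02846 stood at 1.37 ± 0.13 and RDRS00312 at 0.22 ± 0.07 (SE), both well above background in both strains. RDRS00311, with wild-type not well above background in stationary phase, stood at a fitted 2.65, which scaling between arrays turned to -0.02 (adjusted p = 0.975). The group median was 0.06 and camera gave an adjusted p of 0.0283, or 0.0906 with an estimated correlation. Scaling between arrays also turned the group median, to -0.07. In wild-type RDRS02846 stood at -0.03 ± 0.08 from exponential to stationary phase, whereas in the complemented strain it rose by 1.34 ± 0.08. Of the 12 IDs, 7 were not well above background in stationary phase in wild-type and 4 in the complemented strain, so rises and falls of the group are not counted. Camera gave no call for either course (adjusted p = 0.249 and 0.673). Fry, which does not compare the group with other IDs, gave adjusted p of 4.85e-06 (down) in wild-type and 8.85e-05 (up) in the complemented strain. For the ratio, stationary minus exponential, fry gave 0.000548 (up). It used all 12 IDs, also those not well above background.

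Among IDs in the order of their numbers, those more than 2-fold higher in the mean ratio formed 2 long runs. RDRS03632 to RDRS03644, 13 consecutive tested numbers, had a median ratio of 1.36, and RDRS03964 to RDRS03975, 12 numbers, had a median of 1.33. The values of their members lay between 1.10 and 1.60. In exponential phase the run medians were 1.42 and 1.34, and in stationary phase 1.19 and 1.26. The runs were noticed after the data were examined.

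**Figure D4:**
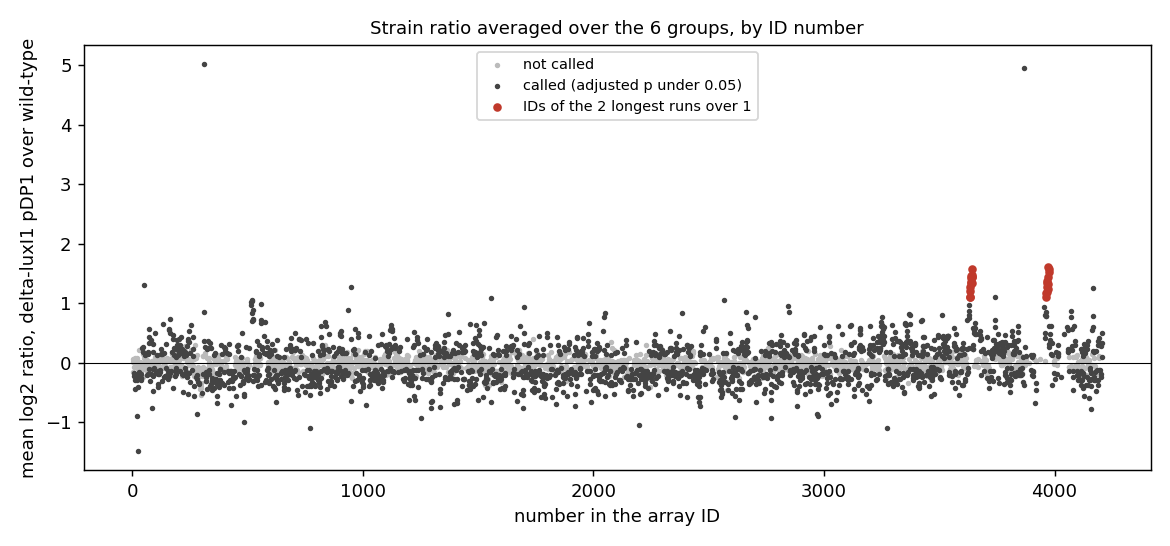
Mean log2 ratio of complemented strain over wild-type (y axis) by the number in the array ID (x axis), with IDs not called in grey, called IDs in dark grey and the 2 longest runs in red. The runs lie between 1.10 and 1.60, and the points near 5 are RDRS00311 and RDRS03868.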

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

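The tests below were chosen only after the result was seen, except for the splits that exchange the strains, which were written down before. For the labelling fault and the OD600 0.6 sample at OD600 0.8, the predictions were written down before their tests. They name the replicates, so the difference between the 2 wild-type samples had been seen by then. Differences between groups drew attention to 1018 IDs whose ratio differed over the groups, 1161 whose ratio differed between stationary and exponential phase, and 317 with a slope over the exponential densities, each by limma's test of the difference itself. The same test singled out RDRS00311 at 2.65 (-0.02 with scaling between arrays), RDRS03868 at -4.12 and RDRS02558 at -2.28 on the log2 scale for stationary minus exponential, and by camera with its preset correlation the PhotoGC group with a median of 0.47, a call that was lost with an estimated correlation (adjusted p = 0.0906). In stationary phase the wild-type signals of RDRS00311 and RDRS03868 were not well above background. For RDRS02558 neither strain was well above background in exponential phase.

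The wild-type samples of the 2 OD600 0.8 arrays differed by 0.814 (root mean square over IDs), and without both arrays the 1018, 1161 and 317 IDs were 1990, 2377 and 236. A fault of a whole array is argued against because the complemented channels of the same arrays differed only 0.345 times as much. Noise in the wild-type channel of replicate 2 is argued against by its departure from the earlier densities, which followed that of the complemented strain on the other array at r = 0.836 across IDs. A labelling fault in that channel stays open, since a wrongly labelled sample that had made the same change would share this departure. An array of replicate 1 that received RNA of an OD600 0.6 wild-type sample stays open: normalized alone, its distance to the nearest such sample was 1.35 times the largest distance between replicates at OD600 0.1 to 0.6, between the bounds set for a decision. A culture that had not yet entered the change seen in the other 3 samples may be the biological explanation, and it was not tested.

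The strain ratio shared by all densities could be a dye effect, since the dyes were never exchanged. A dye effect of single probes as the whole cause is argued against by the correlation of different probes of an ID. It was r = 0.616 across 3587 IDs, where the highest of 1000 random pairings gave 0.0570. This leaves room for a part of the ratio that differs between the probes of an ID. A dye effect constant for an ID cannot be told apart from a constant strain difference, because 0 arrays had exchanged dyes. The F test was passed by 36.4% of the 1974 IDs (719), against 28.4% of all tested IDs, which shows changes with density but leaves the shared part of their ratio open too. Of 100 splits that exchange the strains on arrays at random, the real one included, 1 gave as many called IDs, the real one with 1974, and the highest of the others gave 1311. Exchanging 1 of 2 replicates also widens the spread within a group, and a constant dye effect would give the same outcome. The splits show that ratios kept their direction across arrays, not whether strain or dye set it.

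The 2 runs of consecutive IDs that were over 2-fold higher are argued not to be a chance order of the IDs, since 0% of 10000 random orders gave a run as long and the longest had 3 IDs. A candidate explanation is that the runs are near-identical copies whose transcripts bind each other's probes: at an offset of 332 numbers the wild-type levels of 12 aligned IDs correlated at r = 0.889, as high as 0.221% of 7676 random window pairs, though copies regulated alike would give the same. A constant difference in gene dosage as the whole cause is argued against for 15 of the 25 IDs. Their ratio changed between exponential and stationary phase, 9 downward and 6 upward, as it did for 32.3% of all tested IDs. The F test over the groups passed for 5 of 13 and 3 of 12 IDs of the runs. As a part of the cause gene dosage stays open, since such changes can add to a constant part. This count replaced a first version of the test, whose median of -0.10 with quartiles of -0.50 and 0.21 decided nothing. Apart from gene dosage, no biological explanation was tested.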

How the results depend on the processing

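Only the omission of both OD600 0.8 arrays and the growth courses within slide 2 were chosen after seeing the data. Each count of IDs stayed within 1.5 times of that reported under no background correction, processed signals, median centring, no filter, the median of the probes and the matrix values, where run, while the density counts rested on the spread that the OD600 0.8 arrays add. Where not stated, the cause was not tested. With the replicate block the mean ratio gave 1973 IDs, and the F test 924. The labels give no pairing beyond the number, which is also the row on the slide: over 15 pairs of groups the replicate differences correlated at -0.123 to 0.350, 8 of them over 0.1, the level that all would have to pass to be treated as pairs. Signal over background limits the stationary phase, where as little as 38.9% of wild-type IDs were well above background.

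Stricter thresholds call fewer IDs by construction. At an adjusted p of 0.01 the counts were 226, 274, 274, 260 and 1250 at OD600 0.1 to 0.8, 823 in stationary phase, 640 for stationary minus exponential, 50 for the slope, 354 for the F test and 328 for wild-type OD600 0.8 minus 0.1. With at least 2-fold they were 40 for the mean, 44, 50, 53, 50 and 298 at OD600 0.1 to 0.8, 149, 137 and 1 for stationary, stationary minus exponential and slope. For the growth courses they were 1437 and 99 in wild-type and 1140 and 805 in the complemented strain. The filter on both channels tested fewer IDs (1455) and gave 937 for the mean, 316, 322, 340, 331 and 883 at OD600 0.1 to 0.8, 754 in stationary phase, 583 for stationary minus exponential and 613 for the F test.

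Scaling between arrays gave 1594, 1588, 1661 and 1574 at OD600 0.1 to 0.6, 823 slopes (336 up, 487 down, against 167 and 150) and 1653 in the F test. It turned stationary minus exponential to -0.0247 for RDRS00311 and to -0.0728 for the QSense median. Scaling gives the ratios of all arrays the same spread. Their SD over IDs was 0.482 and 0.483 in stationary phase, 0.326 to 0.344 at OD600 0.1 to 0.6, and 0.900 and 0.411 at OD600 0.8. Scaling therefore shrinks stationary ratios relative to those at OD600 0.1 to 0.6. How much of the turn this explains was not tested. Array weights gave 2096, 2095, 2229, 2056 and 12 at OD600 0.1 to 0.8, 2381 in stationary phase, 24 slopes and 1756 in the F test, with a weight of 0.0401 for the OD600 0.8 arrays, which shows the cause. Only the arrays of a density gave 2049, 2180, 2266, 1941, 1 and 2329 from OD600 0.1 to stationary phase. Without both OD600 0.8 arrays the counts were 1950, 2008, 1954 and 1945 at OD600 0.1 to 0.6, 2628 in stationary phase, 2377 for stationary minus exponential and 1990 in the F test, and the slope of RDRS00265 turned to 0.00918. Processed signals turned the majority at OD600 0.2, with 308 higher and 333 lower IDs against 380 and 259, at 0.4, with 298 and 364 against 331 and 271, and at 0.6, with 285 and 342 against 296 and 287, and the cause was not tested. The near-even split at 0.6 also turned, among others, without background correction (309 and 334), with no filter (324 and 350), with the matrix values (246 and 264) and without both OD600 0.8 arrays (957 and 988). The majority turned too at 0.4 with the filter on both channels (158 and 182), at 0.1 and 0.4 with only their arrays (1022 and 1027, 1125 and 1141), for the slope without OD600 0.8 replicate 1 (500 and 670), replicate 2 (1073 and 1526) or both (102 and 134), for the complemented growth course with no filter (1724 up, 1631 down) and for its course from OD600 0.1 to 0.8 without OD600 0.8 replicate 1 (1428 and 1424).

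Within slide 2, with fewer arrays, stationary minus exponential gave 678, the slope 31 and the F test 383. The slide as a block gave 44 slopes (31 up, 13 down), and 1001 in the F test. Within slide 1 the PhotoGC median of the mean ratio turned to -0.0184, on densities where it lay near 0. With an estimated correlation camera lost PhotoGC in the mean (0.11), in stationary minus exponential (0.47), in wild-type growth (-0.81) and in complemented growth (-0.34), because its estimate was 0.128 to 0.264 against a preset of 0.01. The QSense call for stationary minus exponential (0.0622) was lost with an estimated correlation, with array weights (0.0622), with the median of the probes (0.0671), without background correction (-0.0259) and without both OD600 0.8 arrays (0.0295), and the cause was not tested.

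Leaving out each array in turn gave 116 to 1950 at OD600 0.1, 148 to 2008 at 0.2, 148 to 1954 at 0.4, 131 to 1945 at 0.6, 610 to 2628 in stationary phase, 474 to 2515 for stationary minus exponential, 27 to 2599 slopes, 344 to 3109 in the F test and 165 to 2692 for wild-type OD600 0.8 minus 0.1. A lone array is assumed to vary like the other groups. The QSense median for stationary minus exponential lay between 0.0354 and 0.0897. The group's call by camera was lost without OD600 0.8 replicate 1 (median 0.0897) or replicate 2 (median 0.0759). Counts that stayed within 1.5 times were the mean ratio (1758 to 2957 without each array), OD600 0.8, both stationary minus exponential growth courses and the complemented course from OD600 0.1 to 0.8.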

Other observations

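From OD600 0.1 (slide 1) to 0.8 (slide 2) in the complemented strain, RDRS00265 fell by 2.53 ± 0.26 (SE) on the log2 scale (adjusted p = 3.67e-06), and RDRS00837 rose at least 3.36-fold from background. In wild-type the levels of RDRS00265 at OD600 0.8 were 17.40 in replicate 1 and 16.23 in replicate 2, against 16.77 and 16.78 at OD600 0.1, and RDRS00837 was not well above background at either density. These IDs were named for their strain ratio at OD600 0.8, where the wild-type replicates differed.

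The ratios of the replicate 1 array at OD600 0.8 correlated across IDs with those of the OD600 0.1 to 0.6 arrays at r from 0.223 to 0.316, and with the stationary arrays at r from -0.133 to -0.0851. The replicate 2 array gave r from 0.536 to 0.618 with the former and 0.297 to 0.328 with the latter, and the replicates gave r = 0.522 with each other. Among the OD600 0.1 to 0.6 arrays r lay between 0.849 and 0.955, and the stationary replicates gave 0.937. IDs are not independent replicates. A pair of neighbouring IDs, RDRS00517 and RDRS00518, had a median mean ratio of 1.04, with 1.27 in exponential phase and -0.09 in stationary phase.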
